A study of Bos taurus with 6 samples.

How the data were processed

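Ovarian cortical strips from cattle were cultured at 38.5 °C under 5% CO2 for 8 days, with medium supplementation at 25% on alternate days, per the labels' protocols. Total RNA was extracted with a TRIzol-based kit that included DNase treatment and purified on a second kit. Libraries were made with QuantSeq FWD, a kit that primes at the poly(A) tail and keeps strand, with a module that adds unique molecular identifiers, and were sequenced as single 100-base reads on one lane. FastQC 0.11.2, Trimmomatic, STAR 2.7, featureCounts and DESeq2 are named in the submitters' processing notes, with the cattle assembly ARS-UCD1.2. Whether the molecular identifiers were used to remove duplicates, the annotation release and the counting parameters are not given in the sources used here. The units counted are therefore called reads. The exact interval of a ratio of read rates treats reads as independent and covers counting error only. The intervals of differences from limma rest on the spread between libraries.

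One table of 15265 genes by 6 libraries was analysed, and each of its columns was matched to a sample by its title. Its deposited values are on a log2 scale: the authors scaled the libraries and applied a transformation that the sources used here do not name. The values run from a floor of 2.67, shared by all libraries, to 17.5. Each library's low values rise in discrete steps, and the steps of all 6 libraries lie on a single curve, as whole counts divided by a size factor do after one transformation. The reads were therefore recovered from the table alone by aligning the ladders of 70 to 173 consecutive steps and extending the curve upward. Every step checked against the deepest library was whole within 0.1 reads. Among distinct values beyond the ladders, 100% up to 500 reads, 99.7% above 500 and up to 1000 reads and 70.3% over 1000 reads were whole within that tolerance. The last class holds 0.427% of the values above the floor, for which the reads are approximate. It includes the 2 most abundant genes, with 39.6% to 51.3% of the reads of a library. Library totals, CPM and shares of reads thus rest in part on approximate reads. On a simulated table with another transformation and other depths, all values up to 500 reads were returned (100%), and larger ones within 0.027%. The scaling factors implied by the table, rounded to 3 digits, equalled the median-of-ratios factors of the recovered reads. Recovered reads gave the depth, the filter, CPM and the alternatives, while the main test used the deposited values.

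Genes were kept if they had at least 15.1 CPM, equal to 10 reads in a library of median size, in 3 or more libraries and at least 15 reads in all, which left 4919 genes. High NEFA was compared with control in all 6 libraries with limma 3.58.1 in R 4.3.3, as a linear model of group with empirical Bayes moderation, an intensity trend and robust shrinkage, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This departs from the design fixed before the data were examined, which named a quasi-likelihood count model as the main test wherever counts were deposited or could be recovered, and limma on log2(value + 1) otherwise. Reads could be recovered here, but that count model was not run, because the deposited unit is a log scale; limma-voom and a quasi-Poisson F test on the recovered reads were run in its place as alternatives. The values already being on a log scale, no further log or pseudocount was applied in the main test. A difference on this scale is close to a log2 fold change for abundant genes and understates it for rare ones. Standard errors are from the moderated fit. Library measures were compared by exact permutation tests in scipy 1.17.1.

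The rule for naming genes, also fixed beforehand, took the 10 genes with the smallest p in each direction among those with a symbol, an adjusted p under 0.05 and groups that do not overlap, and the 5 with the smallest p, as values, where none passed, with further members from each gene list. The table gives Ensembl identifiers alone, and 0 of 15265 matched the table of gene names used here, which covers 37063 genes of another assembly without Ensembl identifiers. The 2 genes with the smallest p in each direction are therefore given by identifier, without position or annotation. The most abundant gene is given by identifier for its share of reads, and was chosen after its values were seen. Without names, the 32 gene lists fixed beforehand and the share of mitochondrially encoded transcripts were not analysed here.

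The pipeline was tested on simulated data: 20 draws of libraries with negative binomial counts at the real means and depths, and 20 draws of the real reads thinned in one group, each with 200 genes changed by 2-, 4-, 8- or 16-fold. In the first, 159 of 3156 calls were on unchanged genes. In the second, 2 of 1379 calls were on genes that had not been thinned. Whether those genes differ between the real groups is unknown, so this count does not measure false calls. The libraries were checked for duplicates: the chi-square statistic per degree of freedom between pairs lay between 4.52 and 15.3, so no pair agreed within sampling noise. Alternatives comprised other scalings (median of ratios, trimmed mean of M-values, upper quartile), log2 of scaled reads with pseudocounts of 0.1, 1 and 5, limma-voom and a quasi-Poisson F test on the recovered reads, other filters, no robust shrinkage, other thresholds, the replicate number as a block, total reads as a covariate, and leaving out each library. To compare libraries at equal depth, the 2 most abundant genes were set aside and the remaining reads thinned to 203883 per library in 20 draws, and log2(reads + 1) was tested in the same model. An SD over these draws covers the random thinning alone, not the spread between samples.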

Results

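Strips of bovine ovarian cortex, the outer layer of the ovary, were taken from abattoir ovaries after removal of follicles and cultured for 8 days with or without a mixture of palmitic, stearic and oleic acid at 0.72 mM. These are the main non-esterified fatty acids (NEFA) that circulate at raised levels in cows mobilising body fat. RNA from 3 control and 3 high NEFA cultures was profiled by 3′-tag RNA sequencing, in which reads are counted near the 3′ end of transcripts. The libraries carry the replicate numbers 2, 4 and 5 in each group. The labels do not say whether replicates came from separate ovaries, so p-values measure the spread between these samples, part of which may be technical. The groups follow the treatment label and the titles; the treatment protocol in the labels describes the fatty acid mixture for control samples too, so what the controls received is taken from their group label alone. The question was which transcripts of the cortex differ in abundance after exposure to the fatty acids.

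The table held 15265 genes. The reads recovered from its transformed values are approximate for values over 1000 reads. They summed to 374291, 418701 and 908105 in control replicates 2, 4 and 5. In high NEFA replicates 2, 4 and 5 they summed to 635314, 693011 and 1168402. At least 1 read was found for 10393, 9157 and 11781 genes in these control libraries and for 11769, 11405 and 11938 genes in the high NEFA libraries. Controls averaged 10444 ± 1313 detected genes (SD, n = 3) and high NEFA cultures 11704 ± 272 (SD, n = 3), a difference that did not exceed the spread (exact permutation test, two-sided, p = 0.3). Reads also did not differ detectably in number between the groups (p = 0.3, same exact test). With 3 libraries against 3, the smallest p this exact test allows is 0.1. The 4919 genes that passed the low-count filter held 96.1% of all reads.

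**Figure D1:**
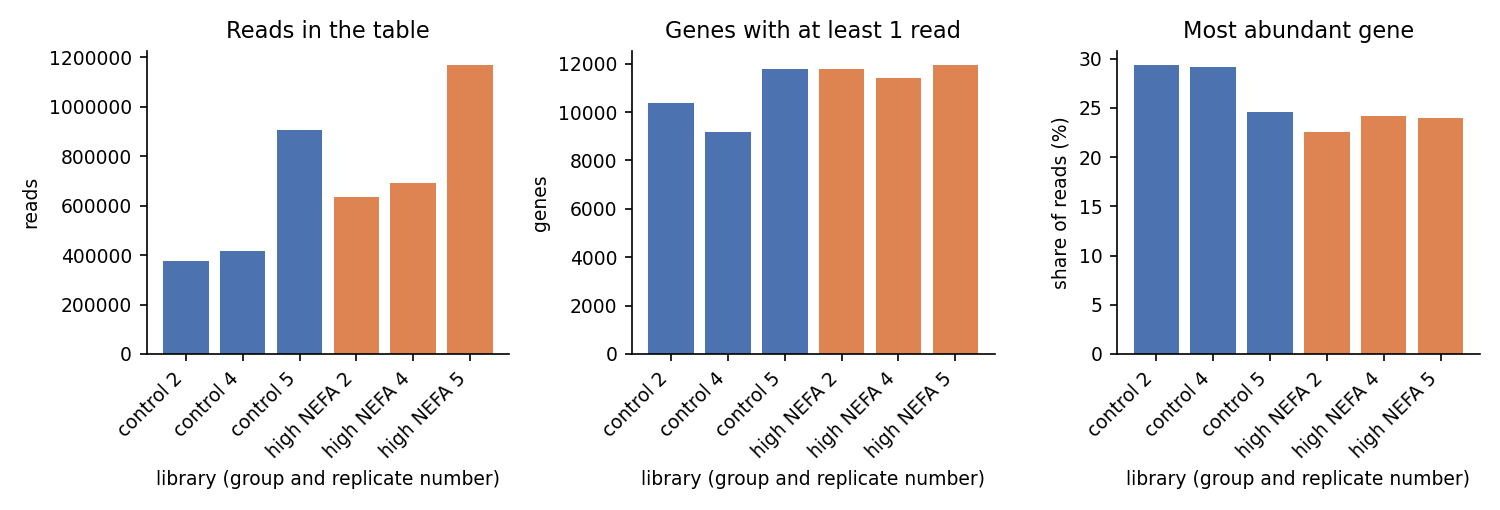
Reads in the table, genes with at least 1 read, and share of reads from the most abundant gene (%) in each library; blue bars are control and orange bars high NEFA libraries. Reads run from 374291 to 1168402, and the most abundant gene's share is 24.6% to 29.3% in the controls against 22.5% to 24.1% in the high NEFA libraries.

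No gene rose or fell in high NEFA cultures relative to controls at an adjusted p under 0.05, among 4919 genes tested with limma's moderated test and Benjamini-Hochberg adjustment. The smallest adjusted p was 0.943. At an unadjusted p under 0.05 there were 145 genes, 104 higher and 41 lower with the fatty acids, where an even spread of p-values would give 246. A test of the recovered reads with limma-voom also called 0 genes, with 101 at an unadjusted p under 0.05, of which 48 were higher and 53 lower, so the excess of higher genes was not seen with that tool. A quasi-Poisson F test called 0 with 115, 71 higher and 44 lower. The count at an unadjusted p under 0.05 rested on single libraries: it was 571 without control replicate 5, 232 without control replicate 2, 58 without high NEFA replicate 4 and 39 without high NEFA replicate 5, each with 0 genes at an adjusted p under 0.05. The 3 high NEFA values lay above all 3 control values in 246 genes (5.00%) and below all of them in 174 genes (3.54%), where chance gives 5% in each direction.

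Differences in group means were taken on the deposited scale, which understates the fold change of rare genes. The median difference (high NEFA minus control) was 0.04 on the log2 scale, and 2653 genes had a higher mean in the high NEFA group against 2266 with a lower one. Scaling by median of ratios holds this signed median near 0, so it does not measure how large the differences were. A difference of at least 1 on the log2 scale was seen for 69 genes in the upward and 23 in the downward direction, none with an adjusted p under 0.05. Scaling the libraries in other ways moved the median difference to between 0.0065 (upper quartile) and 0.08 (trimmed mean of M-values). By abundance, the median difference was 0.12 in the 1640 least abundant genes, 0.04 in the 1639 genes of middle abundance and -0.05 in the 1640 most abundant genes. These classes held 58, 42 and 45 of the genes at an unadjusted p under 0.05.

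**Figure D2:**
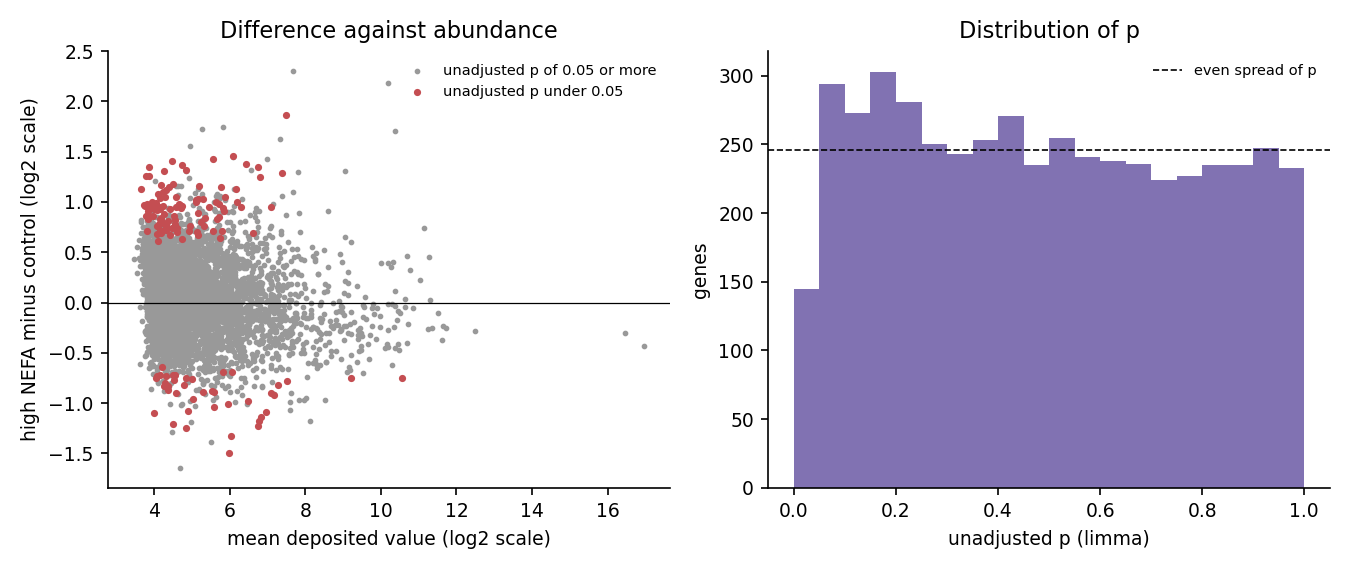
Left, the difference between group means (high NEFA minus control, log2 scale) against the mean deposited value (log2 scale) of each of 4919 genes, with the 145 genes at an unadjusted p under 0.05 in red. Right, the number of genes by unadjusted p, with a dashed line at the 246 genes per bar that an even spread would give; the bar nearest 0 lies below that line.

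The 2 genes with the smallest p in each direction are described by their Ensembl identifiers, because the files do not pair identifiers with names. ENSBTAG00000006523 was measured at 158 ± 15.2 CPM (reads scaled to a common library total) in controls and at 457 ± 79.8 in high NEFA cultures (SD, n = 3 each). All 3 high NEFA libraries, at 398 to 548 CPM, lay above all controls, at 143 to 174. Its difference on the deposited scale was 1.29 ± 0.29 (SE) on the log2 scale, with an unadjusted p of 0.000911 and an adjusted p of 0.943. ENSBTAG00000020729 was counted 7 times over the 3 control libraries and 74 times over the 3 high NEFA libraries. The ratio of its read rates (high NEFA to control) was 7.20, with an exact 95% interval of 3.33 to 18.5 that covers counting error only. The gene was picked for its small p in the same data, so this interval is no separate support. CPM and read rates divide by totals that include the 2 most abundant genes, at 46.0% of reads in controls and 40.6% in high NEFA cultures. At the authors' scaling, limma-voom gave folds of 5.74 for this gene and 2.46 for ENSBTAG00000006523. At that same scaling, the log2 fold of ENSBTAG00000020729 was 2.52 with limma-voom and 2.64 with the quasi-Poisson test. On log2 of scaled reads it was 1.64 with a pseudocount of 5 and 2.92 with one of 0.1. With so few reads, its fold thus depends on the method and not on the scaling alone. On the deposited scale, which compresses low values, ENSBTAG00000020729 differed by 1.35 ± 0.31 (SE, limma adjusted p = 0.943).

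In the opposite direction, ENSBTAG00000025441 was measured at 167 ± 73.0 CPM in controls and at 60.3 ± 22.7 in high NEFA cultures, a log2 difference of -1.49 ± 0.43 (SE) with a limma adjusted p of 0.943. The lowest control library, replicate 2 at 90.8 CPM, was close to the highest high NEFA library, replicate 5 at 81.3. ENSBTAG00000009617 was measured at 162 ± 65.0 CPM in controls and 67.5 ± 23.9 in high NEFA cultures, with a log2 difference of -1.33 ± 0.41 (SE; limma adjusted p = 0.943). Control replicate 5 and high NEFA replicate 2 hardly differed for this gene, at 94.7 and 94.4 CPM. With total reads per library as a covariate its difference was -0.79 on the log2 scale.

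**Figure D3:**
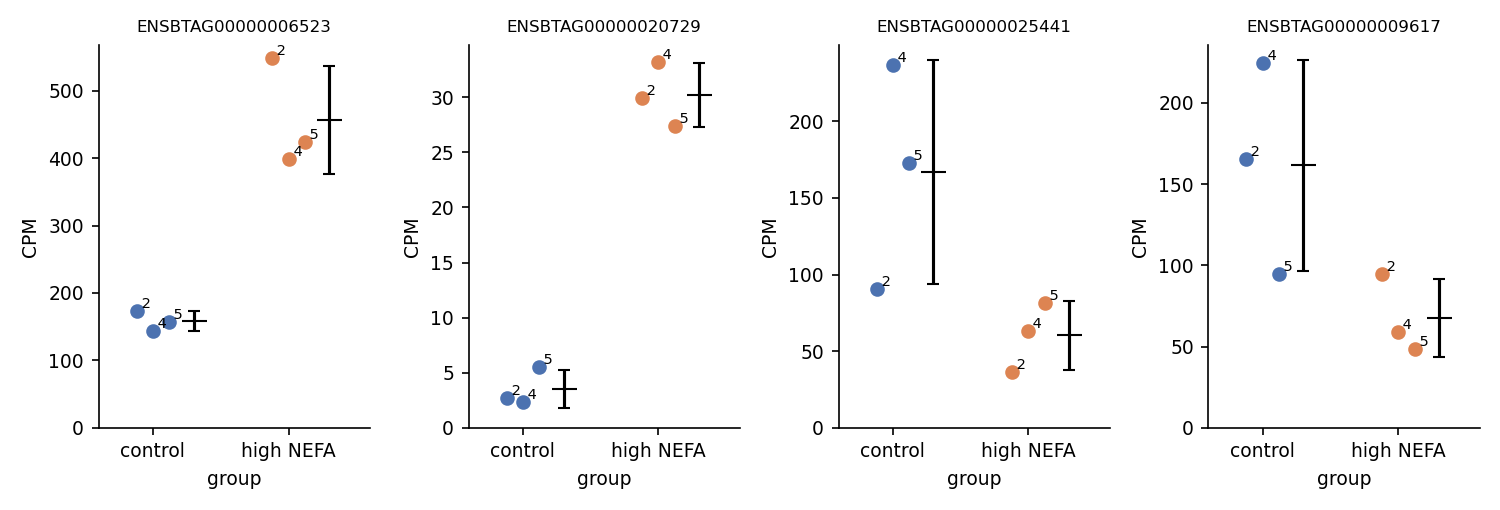
CPM in each library for the 2 genes with the smallest p in each direction; points carry the replicate number, and the bar beside each group is the mean with its SD (n = 3). For ENSBTAG00000006523 the high NEFA libraries lie at 398 to 548 and the controls at 143 to 174.

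A pair of genes took 39.6% to 51.3% of the reads of a library. The most abundant gene, ENSBTAG00000043570, took 27.7% ± 2.69 of reads in controls and 23.6% ± 0.91 in high NEFA cultures (SD, n = 3 each). Its share was lower in all 3 high NEFA libraries than in any control, the smallest p that 3 against 3 libraries can give (exact permutation test, two-sided, p = 0.1; 0.36 after Benjamini-Hochberg adjustment over 6 library measures). In the test over all genes it had a log2 difference of -0.43 ± 0.24 (SE; limma adjusted p = 0.943). The second gene took 18.4% ± 3.32 of reads in controls and 17.1% ± 1.09 in high NEFA cultures (exact permutation test, p = 0.8).

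Control cultures resembled each other less, on average, than they resembled high NEFA cultures. Pearson's r across the 4919 genes was 0.78 to 0.86 between controls, 0.91 to 0.93 between high NEFA libraries, and 0.79 to 0.96 between libraries of different groups, with means of 0.82, 0.92 and 0.87. Genes are not independent replicates, so these values only describe the libraries. The highest of the 15 correlations, 0.96, joined control replicate 5 and high NEFA replicate 5. Control replicate 4 had the lowest mean correlation with the other libraries, 0.81 against 0.84 to 0.90 for the rest. It lay at least 1 log2 unit below all 5 other libraries in 247 genes and above all of them in 125, while the next library, control replicate 2, did so in 53 and 47 genes. The first principal component, with 47.6% of the variance, separated control replicate 4 from the others, and the second, with 29.3%, separated control replicate 2. The treatment groups accounted for 19.3% of the variance over genes, and 5 of the other 9 ways to divide the 6 libraries into 3 and 3 accounted for more, up to 31.1%.

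**Figure D4:**
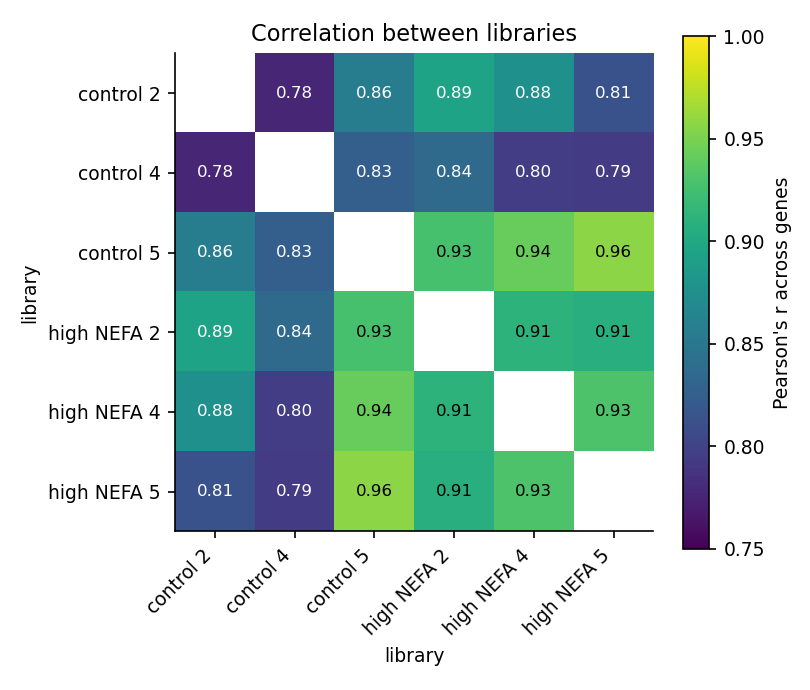
Pearson's r across 4919 genes between each pair of libraries, on the deposited log2 scale. Control replicate 4 has the lowest mean correlation with the others, 0.81, and the pair of libraries numbered 5 has the highest value, 0.96.

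The SD between replicates was larger in controls than in high NEFA cultures for 72.8% of genes, with medians of 0.45 and 0.28 on the log2 scale. A gene had a median of 14, 11 and 36 reads in control replicates 2, 4 and 5. In high NEFA replicates 2, 4 and 5 these medians were 26, 28 and 49. Counting error is thus larger in control replicates 2 and 4, and its part in the SD was not tested. The 95% interval of a gene's difference had a median half-width of 0.73 on the log2 scale, and it lay wholly between -1 and 1 for 2464 genes (50.1%). The deposited scale understates the fold change of rare genes, so for them these bounds do not exclude a 2-fold change. When known folds were placed in 200 genes of the real libraries per draw by removing reads from one group, 1.0% of genes with a 2-fold change, 25.5% with a 4-fold change, 50.0% with an 8-fold change and 61.2% with a 16-fold change were called. In libraries simulated from negative binomial noise alone, these shares were 22.1%, 81.4%, 96.5% and 99.7%. The folds were placed differently there: one group was raised and the other lowered, with the mean over the 6 libraries kept. The gap between the 2 sets of shares is thus not one of noise alone. The fitted difference of genes with a 16-fold change, 4 on the log2 scale, had a median of 1.81 in the real and 2.32 in the simulated libraries (mean over draws). Most changes of 2-fold and 4-fold, and 50.0% of those of 8-fold, were thus missed when placed in the real libraries by removing reads. The absence of calls therefore does not show that changes of these sizes were absent. Removing reads lowers the abundance of the changed genes, and changes that add reads were not tested.

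**Figure D5:**
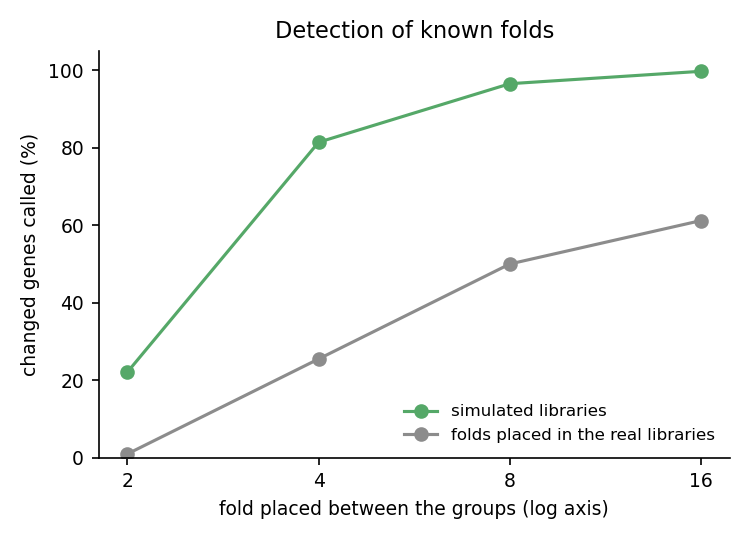
Share of genes with a known fold between the groups that were called at an adjusted p under 0.05 (%), against the fold (log axis). Simulated libraries are green, and real libraries with folds placed by removing reads from one group are grey (4919 genes, 20 draws of 200 changed genes). At 4-fold, the shares are 81.4% and 25.5%.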

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

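The quasi-Poisson test, library quality weights, total reads as a covariate and leaving out both libraries numbered 4 were chosen after seeing the data. Under all 23 alternatives run, the count of genes with an adjusted p under 0.05 (under 0.1 in one of them) was 0, and the smallest adjusted p among them was 0.385, without control replicate 5. Some of these could hardly differ from the main test. Median-of-ratios scaling repeats the authors' factors, the threshold of 0.1 reuses the main fit, and a minimum difference is stricter by design. Their counts of 0 are no separate support. Genes at an unadjusted p under 0.05 numbered 145 in the main test. Leaving out single libraries gave 39 (without high NEFA replicate 5), 58 (without high NEFA replicate 4), 118 (without control replicate 4), 163 (without high NEFA replicate 2), 232 (without control replicate 2) and 571 (without control replicate 5). The count was 448 of 15265 genes with no filter, 271 of 7952 genes with at least 5 CPM in 3 libraries (planned as a stricter filter, but laxer than the main one), 77 without both libraries numbered 4, 98 with quality weights and 28 with total reads as a covariate. A minimum log2 difference of 0.5 left 7. The split of unadjusted genes into higher and lower was 104 to 41 in the main test, 126 to 30 with the trimmed mean of M-values, 77 to 43 on log2 of scaled reads with a pseudocount of 1, and 48 to 53 with limma-voom; the cause was not tested. None of the 4 genes given by identifier changed direction or reached an adjusted p under 0.05 in any alternative.

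The replicate numbers were not treated as pairs in the main test, because the labels do not describe them as pairs. Deviations from the group means correlated at 0.18 for number 2, -0.16 for number 4 and 0.43 for number 5. Only number 5 gave every library its best partner. A criterion of a correlation over 0.1 for every number, written after values had been seen, was not met and did not decide the question. With the replicate block, 0 genes were called and 239 had an unadjusted p under 0.05. The difference of -4.12 percentage points in the share of reads of the most abundant gene cannot change with the block, while its exact p went from 0.1 to 0.25 (sign flips, the smallest p that 3 pairs can give). It was -5.68 to -3.30 when single libraries were left out. The planned quasi-likelihood count model (edgeR) was not run, because the deposited unit is a log scale. This departs from the design, since reads could be recovered. The gene list tests were not run, for want of gene names. The 1640 least abundant genes had a median of 13.8 reads per library and the 1640 most abundant 82.4, with median 95% interval half-widths of 0.74 and 0.72 on the log2 scale; detection was not tested by abundance.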

Other observations

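The tests of labels swapped between the groups, of a shared source behind every replicate number and of other splits of the libraries were chosen or written down after the values they rest on had been seen. The treatment split of the 6 libraries gave 145 genes at an unadjusted p under 0.05, and 6 of the 10 splits into 3 and 3, the real one included, gave as many. The highest of the other splits gave 705. With 10 splits, a share under 0.05 cannot be reached. At an adjusted p under 0.05 the real split gave 0 genes and the highest of the others 1 (limma).

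The split with 705 genes set control replicates 2 and 4 and high NEFA replicate 2, the 3 libraries with the fewest reads, against the 3 with the most. It was picked as the highest of the 10 splits, one of which must be highest, and had 0 genes at an adjusted p under 0.05, so a chance maximum stays open, although a count several times that of the treatment split may point to a structure of the samples. Every library was then thinned to 203883 reads outside the 2 most abundant genes. This split still gave 596 ± 11.6 genes (SD over 20 draws) and the treatment split 168 ± 7.33. The difference of 428.2 genes argues against the number of reads alone. Thinning does not equalise distinct molecules, so differences in their number stay open. At an adjusted p under 0.05 (limma) the treatment split had 0 genes in all 20 draws and the depth split at most 1. A property of the strips or of their RNA that goes with library yield was not tested, and the treatment stays open for part of the difference, since 2 of the 3 shallowest libraries are controls.

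Control replicate 4 stood apart from the other libraries. At equal depth its mean correlation with them was 0.73. Its distance from the lowest of the other means was -0.0464 with an SD over draws of 0.0010, which argues against a lower number of reads alone. Thinning equalises reads, not distinct molecules, and whether duplicates were removed is not known, so a lower number of molecules stays open. Control replicate 4 also held 9155 genes at that depth, against 9928 to 10449 in the other libraries. Labels swapped between the groups stay open: at equal depth it correlated at 0.77, 0.72 and 0.72 with high NEFA replicates 2, 4 and 5 and at 0.71 and 0.75 with control replicates 2 and 5, and its shortfall from the lowest correlation between 2 high NEFA libraries (-0.0646) would arise for any library that stands apart. The makeup of the strips and the quality of the RNA may also differ in this library, and neither was tested.

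Control replicate 5 and high NEFA replicate 5, the deepest library of each group, were the most alike pair. At equal depth their correlation was still the highest of the 15, at 0.89. It lay above the next by 0.0141 with an SD over draws of 0.0028, which argues against a similar number of reads alone. A shared source behind every replicate number stays open. The deviations from the group means of the libraries numbered 4 correlated at -0.159, but this pair holds control replicate 4. The 6 pairs of different numbers spread from -0.39 to 0.18. Deviations sum to 0 within each group, so all these correlations are tied to each other and the spread is no independent yardstick. A shared ovary, culture or processing day may thus explain the pair, for number 5 alone or for all numbers. Some pair of the 15 must be the highest, so chance stays open too. Control replicate 5 also had the highest mean correlation of any library with the others at equal depth, 0.834. With high NEFA replicate 4 it correlated at 0.878.

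The high NEFA libraries were also more alike than the controls at equal depth, with correlations of 0.84 to 0.86 against 0.71 to 0.79. Each range covers 3 pairs that share libraries, and the difference was not tested.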
